A study of Mus musculus with 2 samples.

How the data were processed

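RNA from cells labelled as small intestinal stem cells was compared between a wild-type and a circBtnl1 knockout mouse genotype, with 1 library in each group. Per the labels, total RNA was taken up with a micro-scale column kit, made into libraries with an MGIEasy RNA kit and sequenced on the BGISEQ-500 platform. Whether RNA was selected for poly(A) tails or depleted of ribosomal RNA, and whether strand was kept, was not given in the sources used here.

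The authors deposited 1 table of genes with FPKM values for each library, per the file headers (fragments per kilobase of transcript, scaled to the mapped fragments of the library). The same deposited table gives TPM values, a length-corrected share of all transcripts that summed to 1000000 in each library. All values were rounded to 2 decimals. The submitters' processing notes name the mouse build mm10 and the tools Bowtie2, RSEM and DESeq2, with no version, role or order. Gene-level values of this kind do not separate a circular RNA from the linear transcripts of its host gene, and RSEM-type estimates divide reads among similar genes by a model, so values of near-identical copies are uncertain. TPM is a share of the library, so a few very abundant genes lower the TPM of all others.

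The table held 18068 lines, of which 1 carried no values and was left out, leaving 18067 genes. There were 26 symbols that had been turned into dates, and these were restored from the gene identifiers. Identifiers matched RefSeq genes of assembly GRCm38.p6 for 17947 genes (99.3%), which supplied chromosome positions, and transcript lengths and GC content came from GENCODE M21 and RefSeq transcripts. No column of values was left out (0 columns).

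The design had been fixed before the data were examined for either counts or normalized values. No counts were used here, so the branch for counts, with its counting interval of each ratio, did not apply. For normalized values the design allowed an interval only if whole reads could be recovered. No interval was computed, so the ratios carry no counting uncertainty. That TPM rather than FPKM served as the main unit was chosen after the table was seen. For each gene the ratio was log2((knockout TPM + 0.1)/(wild-type TPM + 0.1)), with the deposited scaling kept. On this log2(value + 0.1) scale the difference of genes with low values is understated. Folds printed in the text are plain ratios of TPM, and none is given against a library listed at 0 or near the level of a few reads. Genes with a mean of at least 1 TPM over both libraries counted as measured (12666 genes). A 2-fold difference (log2 ratio of at least 1, or of -1 or below) was counted as a description of 2 libraries, with no test and no p-value, because genes are not replicates. Transcription factor genes were found by a fixed pattern of gene family symbols, and 391 of them were measured.

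Gene lists were fixed before the data were examined. They covered stem cell and reserve stem cell markers, fetal-like and regenerative markers, Wnt, Notch and BMP genes, proliferation, each differentiated epithelial lineage, immune, stromal, endothelial, neural, erythroid and acinar cells, several stress, immune and metabolic pathways, and butyrophilin-like, regional, histone, ribosomal protein, mitochondrially encoded and Y-linked genes. Of 38 lists, 34 had the 4 or more measured members required. The median log2 ratio of a list was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was said to stand apart at a percentile of at most 2.5 or at least 97.5. This percentile describes these libraries and is not a test over mice.

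Genes named in the text followed a fixed rule. It took Btnl1, Sox9, Atf4 and Lgr5, the 10 genes with the highest and the 10 with the lowest log2 ratio at a mean of at least 5 TPM, leaving out unnamed models, receptor and immunoglobulin segments and pseudogenes, and the 8 highest and 8 lowest transcription factor genes. In each main list and each list that stood apart, it took the 2 highest and 2 lowest members and up to 2 of the most abundant. Some further genes were named beyond the rule, as examples. In the report these were Eno1, Hoxb2, Hoxb6, Hoxb8, Hoxb13, Hoxa13, Hspa5, Ern1, Olfm4, Lyz1 and Defa24. In the further observations they were Col1a1, Col3a1, Sparc, Cd52, Olfm4, Sis, Lct, Alpi, Clca4a, Car1, Hoxb13, Fabp6 and Muc2. Some genes that the rule takes are not reported here.

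Sequencing depth was estimated from the table itself, since a low FPKM value is a whole number of reads divided by transcript length. Over genes with low values, 73.5% of 166 genes in the wild-type library and 75% of 160 in the knockout library lay within 0.15 of a whole number of reads at the best depth, where chance gives 30%. The best depths were 19500000 reads for the wild-type library (19000000 to 21250000 over the length offsets tried) and 17000000 for the knockout library (16250000 to 18750000). At these depths 1 read on a transcript of 1500 bases was worth 0.0708 TPM in the wild-type and 0.0778 TPM in the knockout library. These depths are estimates, and they were used only to set the level below which no fold is given.

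The alternatives were trimmed mean scaling (30% of ratios and 5% of means trimmed at each end), scaling by the median of gene ratios, pseudocounts of 0.4 and 0.02, a stricter floor of 5 TPM, no floor, the FPKM columns, thresholds of 1.5-fold and 4-fold, random lists matched in 10 and 40 bins, means in place of medians, and lists without their most extreme member. Random lists matched on GC content as well, and counts over genes of at least 0.5 TPM in both libraries, were chosen after seeing the data. The calculations were tested on simulated data over 18067 genes for the knockout to wild-type comparison, where 97.5% of 200 genes changed 4-fold were recovered and 6 unchanged genes passed 2-fold. In the same test 3 of 100 lists without a shift and 20 of 20 lists shifted by 1 on the log2 scale fell outside the limits. The simulation held no variation between mice, and its lists were drawn from unrelated genes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.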

Results

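The circular RNA circBtnl1 carries the name of the butyrophilin-like gene Btnl1, and circular RNAs arise when a transcript is joined back on itself. Bulk RNA-seq was performed on cells labelled as small intestinal stem cells from wild-type mice (1 library) and from circBtnl1 knockout mice (1 library), to look for transcription factors whose expression differed. There were no replicates, so every difference below is a difference between 2 libraries, and none could be set against the spread between mice. The estimated depth was 19500000 reads for the wild-type and 17000000 for the knockout library, and 16267 and 16864 genes had a value above 0. The median gene stood at 5.91 TPM in the wild-type and 9.88 TPM in the knockout library. The 10 most abundant genes held 10.7% of all TPM in the wild-type and 7.38% in the knockout library.

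Btnl1 itself (Entrez gene 100038862, chromosome 17, 34377123 to 34386162, GRCm38) stood at 59.3 TPM in the wild-type and 65.4 TPM in the knockout library, a log2 ratio of 0.14. This gene-level value does not separate the circular from the linear RNA, so it does not check the genotype, and circBtnl1 was not analysed here. Its neighbours Btnl2, Btnl4 and Btnl6 were lower in the knockout library, at 18.5 against 6.88 TPM, 133 against 77.7 TPM and 170.5 against 81.1 TPM. The 5 measured butyrophilin-like genes, a family that in the gut maintains intraepithelial lymphocytes, had a median log2 ratio of -0.77 (percentile 0.55 among random lists), and 2 of them were at least 2-fold lower. Without its most extreme member, Btnl2, this list no longer stood apart (percentile 9.95), nor did it with no floor (median -0.040, percentile 18.8) or as a mean (percentile 3.03). Within 500 kb of Btnl1, 49 genes were measured, among them 5 MHC class II genes with a median log2 ratio of -4.74 and 44 others with a median of -0.06.

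**Figure D1:**
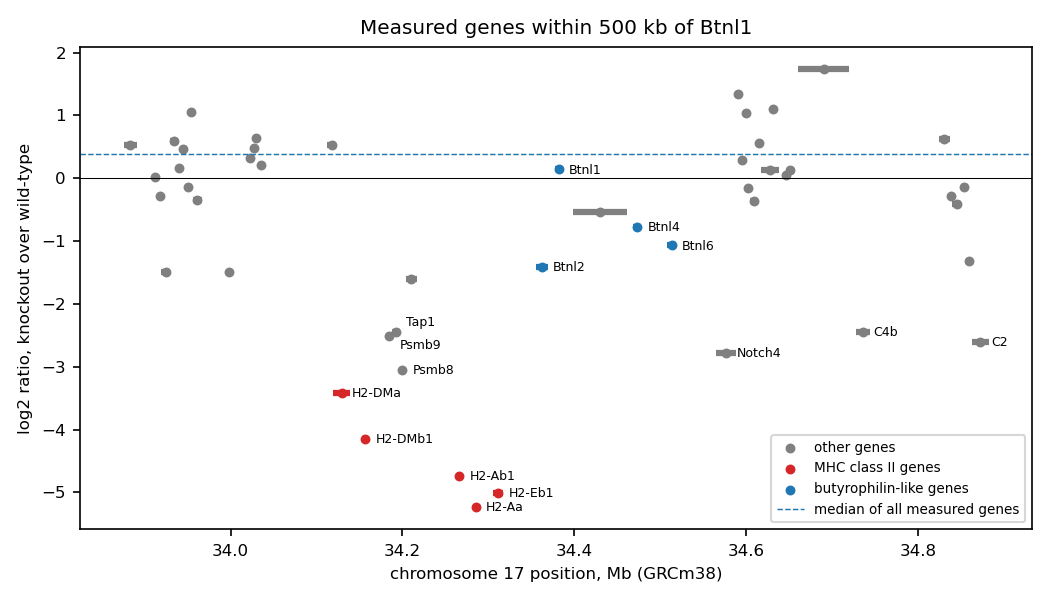
Log2 ratio of knockout over wild-type TPM for the 49 measured genes within 500 kb of Btnl1, against position on chromosome 17 in megabases (GRCm38). Each point is a gene at its midpoint and the bar behind it spans the gene. The dashed line marks the median of all measured genes at 0.39, and the 5 MHC class II genes lie between -3.42 and -5.24.

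The libraries differed at many genes, most of them higher in the knockout library. Of 12666 measured genes, 2924 were at least 2-fold higher and 665 at least 2-fold lower in the knockout library, so that 81.5% of these genes were higher. The highest ratios belonged to genes close to 0 in the wild-type library, among them Spp1 (osteopontin) at 0.3 against 484 TPM, the carbonic anhydrase gene Car6 at 0.08 against 252 TPM, and Ptgs2, which encodes the inducible cyclooxygenase, at 0.21 against 215 TPM. Grem1, a BMP antagonist, stood at 0.07 against 82.4 TPM and Esm1 at 0.05 against 75.1 TPM. Rhox5, Rpl39l and Csn3 were listed at 0 in the wild-type library and stood at 120.3, 117 and 87.8 TPM in the knockout library. Eno1b was also listed at 0 against 278 TPM, a value that is uncertain because the gene is a near copy of Eno1.

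Genes lower in the knockout library included Lrg1, a secreted glycoprotein of the acute phase, at 568 against 0.86 TPM (661-fold lower), and Ido1, the tryptophan-degrading enzyme, at 346 against 1.39 TPM (249-fold lower). Clca4b stood at 803 against 4.86 TPM, the interferon-inducible GTPase gene Tgtp1 at 66.8 against 0.65 TPM, and Nos2, the inducible nitric oxide synthase, at 102 against 1.44 TPM. The lipopolysaccharide-binding protein gene Lbp stood at 38.2 against 0.41 TPM, Krt36 at 35.1 against 0.42 TPM, and the calcium channel gene Trpv6 at 25.1 against 0.35 TPM. The chemokine genes Ccl7 and Ccl8 stood at 12.4 against 0.15 TPM and at 15.97 TPM against a listed 0.

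The median measured gene had a log2 ratio of 0.39, and the counts depended on whether that shift was kept. Under trimmed mean scaling 1687 genes were higher and 1317 lower, and 56.2% of these genes were higher. The median log2 ratio went from 0.76 in the tenth of genes with the lowest mean TPM to -0.05 in the tenth with the highest. Across genes, which are not independent replicates, Spearman's correlation of the ratio was -0.30 with mean TPM, -0.29 with transcript GC content and 0.04 with transcript length. Ratios and folds below include this shift unless given relative to the median gene.

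**Figure D2:**
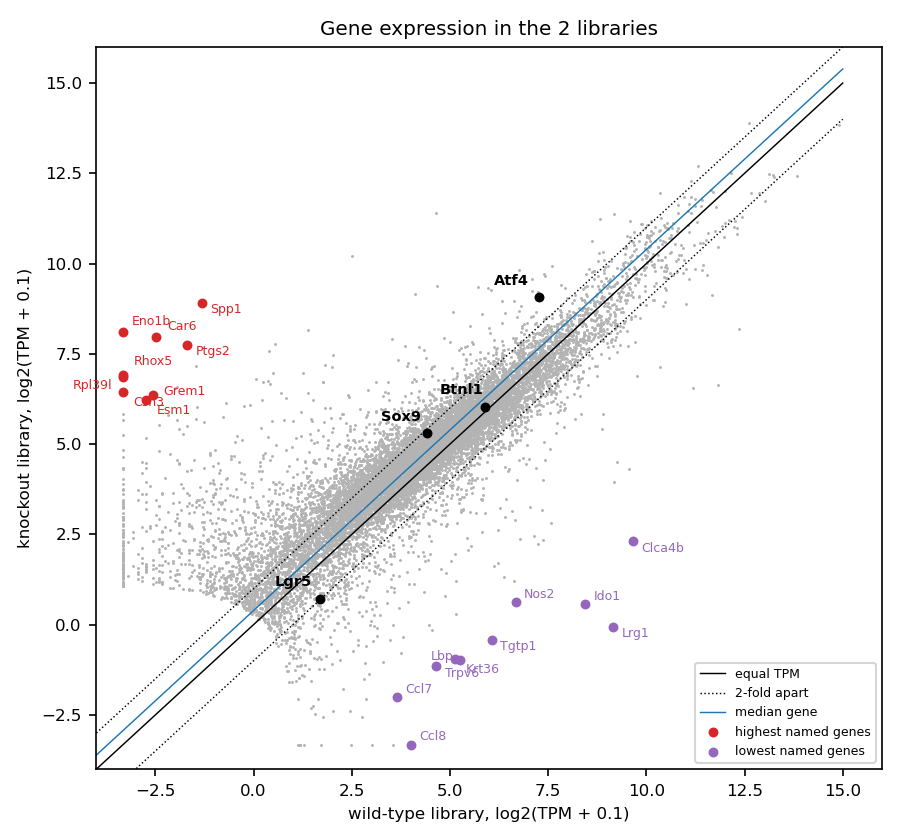
TPM of each of the 12666 measured genes in the wild-type library (horizontal) and the knockout library (vertical), both as log2(TPM + 0.1). The solid black line marks equal TPM, dotted lines a 2-fold difference and the blue line the median gene, with the named genes of the highest and lowest ratios in color and Btnl1, Sox9, Atf4 and Lgr5 in black.

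Transcription factor genes, the class the study set out to compare, differed in both directions. Fosl1, a subunit of the AP-1 factor, stood at 2.52 TPM in the wild-type and 288 TPM in the knockout library (114-fold higher). Atf4, the effector of the integrated stress response, was 3.46-fold higher, at 155 against 536 TPM. Sox9, a crypt and Paneth cell factor, was 1.84-fold higher, at 21.3 against 39.2 TPM, which is under the 2-fold threshold. Relative to the median gene the log2 ratio was 0.49 for Sox9 and 1.40 for Atf4. Atf3 was 7.25-fold lower in the knockout library, at 170.1 against 23.5 TPM. The posterior homeobox gene Hoxd13 was 4.54-fold lower. Hoxb13, also posterior, was lower as well, at 429 against 119 TPM, whereas Hoxa13 was nearly equal, at 22.6 against 20.4 TPM. Some other homeobox genes were higher, such as Hoxb6 at 25.7 against 91.6 TPM. The genes from Hoxb2 to Hoxb8 had log2 ratios of 1.16 to 1.90. Whether both libraries came from the same position along the gut was not tested.

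Of 391 measured genes that matched a pattern of transcription factor family symbols, 94 were at least 2-fold higher and 21 at least 2-fold lower in the knockout library, and 65 and 53 under trimmed mean scaling. Among genes of this pattern, which leaves out other factors such as Rhox5, the 8 highest ratios apart from Fosl1 belonged to genes at or under 0.22 TPM in the wild-type library. Among these were Foxf1 (0.04 against 22.4 TPM), Bcl6b (0.19 against 38.4 TPM), Zeb2 (0.22 against 12.1 TPM), Creb5 (0.08 against 6.7 TPM) and Nr5a1 (listed at 0 against 3.29 TPM). Foxf1 and Zeb2 are known from mesenchymal cells. At the low end stood Grhl3, an epithelial factor, at 3.34 against 0.33 TPM, the myeloid factor gene Spi1 at 2.03 against 0.24 TPM, and Prdm1 at 8.57 against 1.32 TPM. Hoxd11 and Hoxd12, which neighbour Hoxd13, stood at 2.95 against 0.62 TPM and 2.36 against 0.36 TPM.

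**Figure D3:**
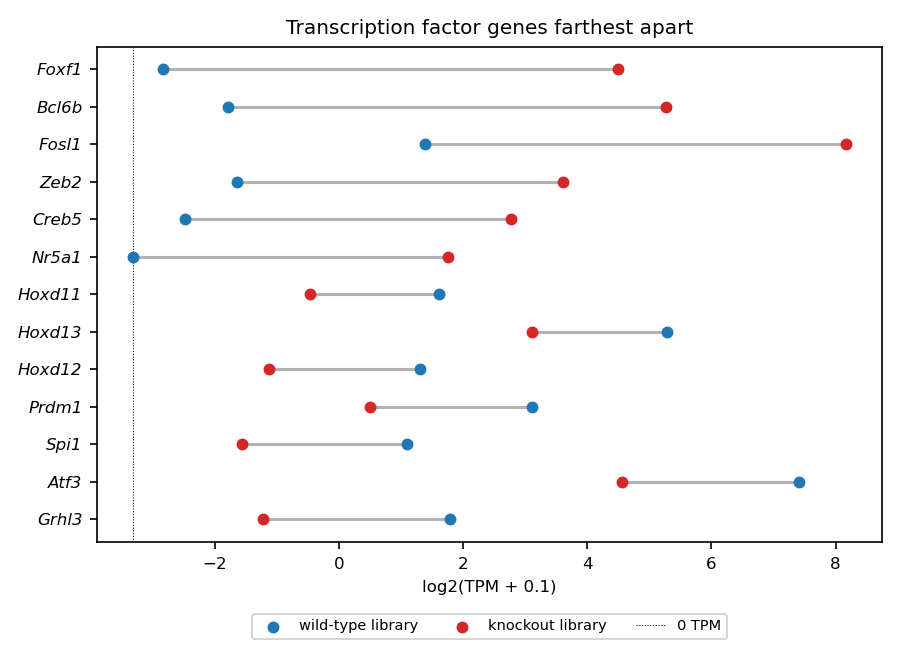
Transcription factor genes of the family pattern, named from among the 8 with the highest and the 8 with the lowest knockout to wild-type ratio, with log2(TPM + 0.1) on the horizontal axis. Blue points are the wild-type library, red points the knockout library, and the dotted line marks 0 TPM, where Nr5a1 stood in the wild-type library.

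Genes of the ATF4 and integrated stress response program were higher together in the knockout library. All 24 members were measured, 19 were at least 2-fold higher and 1, Atf3, was at least 2-fold lower. The pseudokinase gene Trib3 stood at 0.26 against 51.4 TPM, and Aldh1l2, a mitochondrial folate enzyme, was 26.2-fold higher, while Cebpb stood at 79.5 against 50.4 TPM and Nupr1 at 182 against 314 TPM. The list's median log2 ratio was 1.75 (percentile 100), or 1.36 relative to the median gene. The list of unfolded protein response genes had a median of -0.06 (percentile 20.8) and did not stand apart. Of its 17 genes 15 were within 2-fold. The other 2, Hspa5 at 391 against 880 TPM and Ern1 at 12.93 against 29.55 TPM, were at least 2-fold higher.

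Intestinal stem cell markers as a list did not stand apart. Lgr5, the marker of crypt base columnar cells, was low in both libraries, at 3.13 TPM in the wild-type and 1.55 TPM in the knockout library, and Smoc2 stood at 15.5 against 7.72 TPM. Olfm4, another member, lay below the floor, at 0.2 TPM against a listed 0. Markers of differentiated cells were far more abundant, with Krt20 at 2065 against 919 TPM and Zg16 at 8315 against 3413 TPM. The list is therefore not a reading of stem cells alone. Cd44 was 5.54-fold higher in the knockout library and Cdk6 was 3.47-fold higher, while Prom1 stood at 119.6 against 150.2 TPM and Aqp4 at 234 against 257 TPM. Of 19 measured markers 3 were at least 2-fold higher and 1 at least 2-fold lower, and the median log2 ratio was 0.31 (percentile 31.2), or -0.08 relative to the median gene. Reserve stem cell markers likewise did not stand apart, with a median of 0.40 (percentile 40.04) over 6 genes, although they did under a floor of 5 TPM (1.29) and from FPKM (1.34).

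Wnt target genes did not stand apart either (median 0.31, percentile 19.5, 15 genes), although 6 were at least 2-fold higher and none (0) at least 2-fold lower. The list value was 0.11 under a floor of 5 TPM, 0.78 with no floor and 1.01 as a mean, and it did not stand apart in these settings either. Myc was 5.96-fold higher in the knockout library, Lef1 stood at 0.28 against 3.8 TPM and Apcdd1 at 0.11 against 4.28 TPM, while Ccnd1 stood at 88.7 against 90.6 TPM and Ephb2 at 19.7 against 15.4 TPM. Proliferation genes had a median of 0.63 (percentile 99.6, 30 genes), or 0.24 relative to the median gene, and did not stand apart as a mean (0.51). Of these, Bub1 was 2.47-fold and Pcna 2.40-fold higher, Ccnb2 stood at 71.4 against 38.4 TPM, Plk1 at 101 against 77.9 TPM and Ube2c at 217 against 216 TPM. No proliferation gene (0 of 30) was 2-fold higher relative to the median gene. Fetal-like and regenerative markers had a median of 1.07 (percentile 99.9, 13 genes). Of these, 7 were at least 2-fold higher and 1, Ly6a, at least 2-fold lower. Ereg was 118-fold higher in the knockout library, Ly6a (Sca-1) was 5.77-fold lower, at 3246 against 563 TPM, and S100a6 stood at 1536 against 1671 TPM.

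Markers of differentiated cells differed in both directions. Enterocyte markers were lower in the knockout library as a list (median -0.70, percentile 0, 17 genes), but the size varied with the setting: -0.33 as a mean, -0.16 from FPKM, -0.10 with no floor, and -0.10 under a floor of 5 TPM, where the list no longer stood apart (percentile 8.44). The peptide transporter gene Slc15a1 was 5.31-fold and Krt20 2.25-fold lower, while the fatty acid binding protein gene Fabp2 was 5.6-fold higher, and Fabp1 and the fructose transporter gene Slc2a5 were under 3 TPM in both libraries, at 2.08 against 0.5 TPM and 0.74 against 1.73 TPM. Goblet cell markers did not stand apart (median -0.29, or -0.68 relative to the median gene, percentile 7.7, 14 genes), with 3 at least 2-fold lower. Tff3 was 2.81-fold, Fcgbp 2.62-fold and Zg16 2.44-fold lower, while Clca1 stood at 4098 against 4130 TPM, Spink4 at 1805 against 2727 TPM and Klk1 at 911 against 1791 TPM. Enteroendocrine markers were higher (median 1.12, or 0.73 relative to the median gene, percentile 99.0, 15 genes). Of these, 8 were at least 2-fold higher, and 4 relative to the median gene, but the list did not stand apart as a mean (0.78). Chga was 2.17-fold higher, Neurod1 stood at 0.64 against 3.74 TPM and Pax6 at 0.89 against 3.55 TPM, while Tac1 was 10.3-fold lower and Pyy stood at 195 against 136 TPM.

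Of the Paneth cell list only 5 of 9 genes in the table were measured, and none of the 5 was a defensin. Lyz1, at 0.87 against 0.31 TPM, and Defa24, at 1.1 TPM against a listed 0, lay below the floor. The 5 measured genes had a median of 1.33 (percentile 99.2), and the list was not apart as a mean (0.48). With no floor on low values the median turned to -0.65, and the list stood apart on the low side (percentile 0.26). Ang4, an antimicrobial ribonuclease, was 4.6-fold higher and Pnliprp2 was 3.81-fold higher, Guca2b stood at 56.6 against 54.2 TPM, and Mmp7 was 8.45-fold lower. Tuft cell markers had a median of -0.36 (percentile 0.16, 11 genes), which turned to 0.08 under a floor of 5 TPM, with too few genes for a percentile, and to 0.06 as a mean, where the list no longer stood apart (percentile 3.88). Ltc4s was 2.57-fold lower and Alox5ap stood at 4.09 against 2.38 TPM, while Ptgs1 was 11-fold higher, Rgs13 stood at 0.86 against 2.18 TPM, Avil at 7.29 against 7.7 TPM and Sh2d6 at 12.6 against 12.7 TPM.

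MHC class II genes, epithelial antimicrobial genes and part of the interferon response were lower in the knockout library. All 7 MHC class II genes were at least 2-fold lower (median -4.74, percentile 0). The invariant chain gene Cd74 stood at 3635 against 100.2 TPM (36.3-fold lower), H2-Aa at 580.1 against 15.3 TPM, H2-Ab1 at 612 against 22.8 TPM and H2-DMa at 94.9 against 8.77 TPM, and Ciita, the class II transactivator, was 12.5-fold lower. Of 11 epithelial antimicrobial genes 9 were at least 2-fold lower (median -1.98, percentile 0), among them the lectin gene Reg3b at 5223 against 291 TPM, besides Nos2. Pigr, the immunoglobulin transporter, stood at 1593 against 1780.2 TPM and Retnlb at 1204 against 1571 TPM. Interferon response genes had a median of -0.52 (percentile 0.01, 17 genes), with 6 at least 2-fold lower and none (0) at least 2-fold higher. Gbp2 was 26.0-fold and Iigp1 23.6-fold lower, whereas Oasl2 stood at 384 against 268 TPM, Irf7 at 577 against 474 TPM, Ifit1 at 30.3 against 53.4 TPM and Ifit3 at 13.7 against 24.7 TPM.

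Markers of other cells moved together with these groups. T cell and NK markers were lower in the knockout library (median -0.94, percentile 0, 13 genes), with Gzma 3.28-fold and Cd8b1 2.78-fold lower, Itgae at 2.39 against 1.41 TPM and Ccl5 at 38.7 against 26.4 TPM. Myeloid markers were lower (median -1.27, percentile 0, 10 genes), with S100a8 at 6.22 against 0.64 TPM, S100a9 at 8.04 TPM against a listed 0, Fcer1g at 7.45 against 4.02 TPM, Cd68 at 8.09 against 5.53 TPM, Itgam at 1.86 against 1.32 TPM and C1qa at 2.72 against 2.82 TPM. All 4 measured hemoglobin genes of the erythroid list were lower (median -4.47, percentile 0), with Hba-a2 at 110.4 against 5.06 TPM, Hba-a1 at 74.7 against 3.16 TPM, Hbb-bs at 82.3 against 2.4 TPM and Hbb-bt at 8.12 against 0.63 TPM. Hba-a1 and Hba-a2 are near copies of each other, and so are Hbb-bs and Hbb-bt, so the split of reads within each pair is uncertain.

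Fibroblast and muscle markers had a median of -0.16 (percentile 1.13, 8 genes) and were split, with Col1a2 17.1-fold, Pdgfrb 4.63-fold and Dcn 2.56-fold higher, Acta2 5.01-fold and Des 3.4-fold lower. Under a floor of 5 TPM this median turned to 1.76, and the list stood apart on the high side instead (percentile 99.35). From FPKM (0.078) and as a mean (0.33) the value turned positive and the list did not stand apart. Endothelial markers did not stand apart (median 0.27, percentile 14.9, 4 genes), and enteric neuron and glia markers (3 measured, median 0.17) and B and plasma cell markers (1 measured, -0.12) were too few for a percentile. The 4 Y-linked genes measured were higher in the knockout library (median 4.07, percentile 98.5), though the list no longer stood apart with FPKM values (percentile 95.4) or with random lists matched in 40 bins. Ddx3y stood at 0.04 against 4.27 TPM, Kdm5d at 0.01 against 4.8 TPM, Uty at 0.41 against 4.25 TPM and Eif2s3y at 0.96 against 9.48 TPM, so Y-linked RNA differed between the libraries along with genotype.

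**Figure D4:**
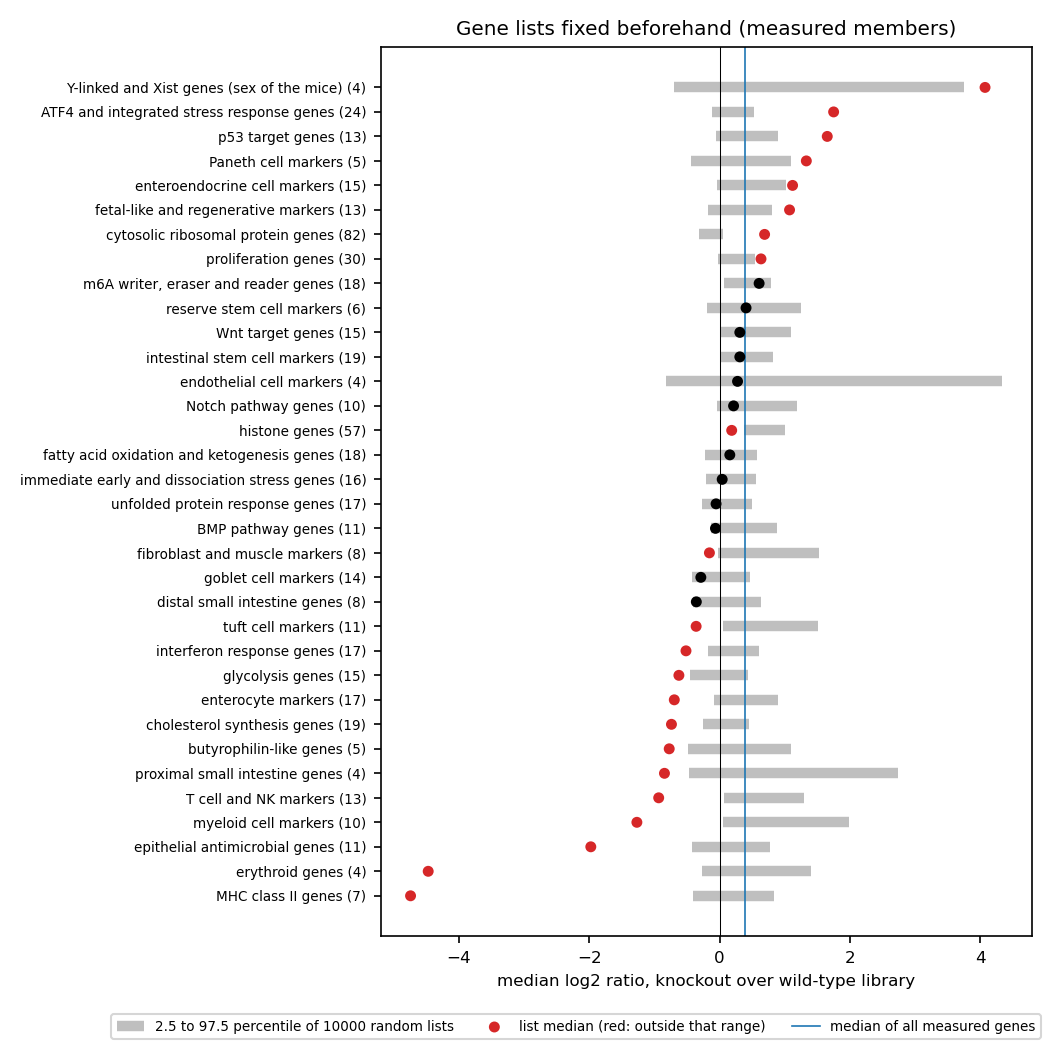
Median log2 ratio, knockout over wild-type library, of the 34 gene lists with at least 4 measured members, with the number measured in brackets. Points are list medians, gray bars the range of 10000 random lists matched on expression within which a list did not stand apart, and the blue line the median of all measured genes at 0.39. The 22 lists in red lie outside their gray bars, 8 higher and 14 lower. Independent lists of unrelated genes would give 1.7. These lists share members and group related genes, so the 22 cannot be read as an excess over that number.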

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

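Of the 22 lists that stood apart, 9 did so in each of the 12 alternatives run on lists: ATF4 and integrated stress response, p53 target, fetal-like, ribosomal protein, MHC class II, antimicrobial, interferon response, cholesterol synthesis and T cell and NK genes. Over 439 list values under alternatives, 27 changed sign, 8 of them in lists that stood apart and 19 in other lists. Of 162 named genes, 39 had a ratio that moved in at least 1 alternative, chiefly under the scalings, whose shift exceeds small ratios. The cause was not tested except where the alternative itself sets it, as a floor does by leaving out genes. No paired analysis was possible because each group had 1 library. The counting interval of each ratio, planned for counts, was not computed, because the values are not counts. Depth limits genes under about 0.3 TPM, which rest on a few reads.

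Genes at least 2-fold higher numbered 1687 under trimmed mean scaling, 1719 under the median of gene ratios and 1907 under a floor of 5 TPM, against 2924. Genes at least 2-fold lower numbered 1317, 1292 and, with no floor, 1176, against 665. Past 1.5-fold 5079 genes were higher and 1344 lower, and past 4-fold 947 and 197. Transcription factor genes at least 2-fold lower numbered 53 under trimmed mean scaling, 51 under the median of gene ratios, 12 under the stricter floor, 34 with no floor and 13 from FPKM, against 21, and those higher numbered 56 under the stricter floor, against 94. Past 1.5-fold they numbered 154 higher and 53 lower, and past 4-fold 42 and 8. Restricted to genes of at least 0.5 TPM in both libraries, a setting chosen after seeing the data, 2485 genes were higher and 601 lower, with 67 and 18 transcription factor genes.

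Stem cell marker and Wnt target medians were both -0.095 under trimmed mean scaling and both -0.080 under the median of gene ratios, with the histone median at -0.22 and -0.20. Under the stricter floor the enterocyte median was -0.10 and no longer apart, and the tuft median turned to 0.078, with too few genes for a percentile. The fibroblast and muscle median turned to 1.76 under that floor, and the list stood apart on the high side (percentile 99.35). The myeloid, erythroid and Y-linked lists had too few genes for a percentile under that floor. With no floor the Paneth median turned to -0.65 and that list stood apart on the low side (percentile 0.26), and the B and plasma cell list stood apart (percentile 0.31). From FPKM the fibroblast and muscle median turned to 0.078. As means, the proliferation (0.51), Paneth (0.48) and enteroendocrine (0.78) lists no longer stood apart, and the tuft (0.061) and fibroblast and muscle (0.33) lists turned positive and no longer stood apart. With random lists matched on GC content as well, chosen after seeing the data, 33 of the 34 lists with a percentile kept their side of the limits, and the Y-linked list did not (percentile 96.8).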

Other observations

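Several further groups fixed before the data were examined differed between the libraries. Of 13 measured p53 target genes 8 were at least 2-fold higher in the knockout library (median 1.65, percentile 99.99), among them Bax, a pro-apoptotic gene, at 50.8 against 159.5 TPM, Phlda3 at 2.5 against 85.3 TPM and Eda2r at 0.05 against 9.09 TPM, while Cdkn1a stood at 713 against 477 TPM, Pmaip1 at 15.5 against 6.51 TPM and Fas at 21.6 against 10.5 TPM. Cytosolic ribosomal protein genes had a median of 0.69 (percentile 100, 82 genes), or 0.30 relative to the median gene, with Rps27 at 479 against 1291 TPM and Rpl41 at 3200 against 4208 TPM. Cholesterol synthesis genes were lower (median -0.74, percentile 0, 19 genes), with Fdps at 474 against 231 TPM, and glycolysis genes were lower (median -0.63, percentile 0.32, 15 genes), with Hk2 at 199 against 72.9 TPM and Gapdh at 8982 against 5733 TPM, although the glycolysis list did not stand apart as a mean (percentile 2.68). Histone genes stood apart on the low side of expression-matched lists (median 0.18, percentile 0.06, 57 genes), and that median was -0.21 relative to the median gene, but they did not stand apart under a floor of 5 TPM (percentile 11.5).

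Proximal small intestine genes were few and low (median -0.85, percentile 0.95, 4 genes), but not apart as a mean (percentile 8.51) and with too few genes for a percentile under a floor of 5 TPM or from FPKM, with Pdx1 at 0.76 against 6.08 TPM and Ada at 17.1 against 9.82 TPM, and distal small intestine genes did not stand apart (median -0.36, percentile 3.88, 8 genes) except against random lists matched in 40 bins (percentile 2.31). Other lists that did not stand apart were Notch (median 0.21, percentile 12.6), BMP (-0.06, percentile 4.26, but apart in 3 of 12 alternatives, with a lowest percentile of 1.36), immediate early and dissociation stress (0.04, percentile 22.5), fatty acid oxidation and ketogenesis (0.16, percentile 47.3) and m6A genes (0.60, percentile 83.8). Pancreatic acinar genes had 3 measured members (median 0.82), and 0 mitochondrially encoded genes were in the table.

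The 9 tests in the next paragraphs were chosen after the results were seen, and so were the gene lists they use, apart from the T cell and NK, myeloid and MHC class II lists. Ratios in these paragraphs are log2 values relative to the median gene. Ranges over genes are not errors between mice.

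In the knockout library 88 genes were at least 64-fold higher, 74 of them under 0.5 TPM in the wild-type library, and together they made up 0.885% of its TPM. Against near-identical gene copies as the whole cause, 17.05% of them were unnamed models, pseudogenes or named copies. For gut fibroblasts or muscle cells, 9 measured genes of 12 abundant in them had a median of -0.37 (range -2.58 to 3.67), below the limit set for a rise. With the deposited scaling 3 of the 9 were at least 2-fold higher and 3 at least 2-fold lower, so a median over this split list cannot decide. Of these Col1a1 stood at 7.95 against 8.05 TPM, Col3a1 at 5.73 against 3.18 TPM and Acta2 at 4.06 against 0.81 TPM, although Col1a2 was higher, at 3.76 against 64.4 TPM, and so were Dcn, at 13.6 against 34.9 TPM, and Sparc, at 11.5 against 29.9 TPM. A separate non-epithelial population stays open: extracellular matrix genes had a median of 1.01 over the 13 of 20 that were measured (range -1.47 to 3.56) but of 0.095 over all 20, and pan-epithelial genes had a median of -0.99 (range -1.65 to 0.21). All 8 epithelial-mesenchymal transition factors were higher (median 4.50, range 2.22 to 6.49). The 21 germ cell and pluripotency genes had a median of 3.97 (range -1.71 to 9.84). These 2 lists hold genes already seen among the highest and cannot count as a test. With 1 library per genotype such a population cannot be told apart from a change within the epithelium that came with the knockout, or from sex, since Y-linked RNA differed between the libraries and 10.2% of the 88 genes lay on X (0 on Y), against 2.91% of all measured genes on X or Y.

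MHC class II genes had a median of -5.13. A neighbouring-gene effect around Btnl1 as the whole cause is argued against by Cd74, which lies on chromosome 18 and stood at -5.57, although 13 of the 44 other measured neighbours were also at least 2-fold lower relative to the median gene. Loss of leukocytes as a whole is argued against by T cell and NK markers, whose median lay 3.81 above that of the class II genes (range -2.09 to -0.94 over 13 genes, against -5.63 to -3.81 for class II). Myeloid markers had a median of -1.66, but their range of -6.74 to -0.34 over 10 genes overlapped that of class II. Loss of antigen-presenting cells as the whole cause is argued against by levels in the wild-type library, where class II genes had a median of 165 TPM, Cd74 stood at 3635 TPM and none (0) of 29 leukocyte and myeloid genes was above 20.3 TPM (Cd52), although most of these were lower as well and a smaller share of the difference stays open. A lower interferon-gamma response also stays open: 24 interferon-gamma-selective genes differed from 18 type I interferon genes by -2.36 in their medians, but that list holds Ciita and genes already seen among the lowest and cannot count as a test, and whether genotype, sex or the animals' surroundings set it was not tested.

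The libraries are labelled small intestine, but genes typical of colon were abundant in both. The 19 small-intestine-enriched genes in the table had a median of 1.92 TPM in the wild-type and 0.55 TPM in the knockout library, against 629 and 523 TPM for 20 colon-enriched genes. Olfm4 stood at 0.2 TPM against a listed 0, Sis at 0.05 against 0.29 TPM and Lct at a listed 0 against 0.04 TPM, whereas Car1 stood at 6272 against 15252 TPM and Hoxb13 at 429 against 119 TPM. Other small intestine genes were present, with Clca4a at 266 against 187 TPM, Alpi at 42.6 against 33.7 TPM and Fabp6 at 50.5 against 8.39 TPM, and some of the colon genes, such as Muc2 and Zg16, are also made in small intestinal goblet cells. Whether the libraries hold tissue other than small intestine stays open, because the lists were written after several of their members had been noticed and cannot count as a test, and culture conditions that alter regional genes were not tested. Whether both libraries came from the same position along the gut was not tested either.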
